A study of Mus musculus with 10 samples.

How the data were processed

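Total RNA of the gastrocnemius, a calf muscle of mixed but mostly fast fibres, was measured in 10 male NMRI mice, an outbred stock, on Affymetrix Mouse Gene 2.0 ST arrays. Of the arrays, 5 are labelled control and 5 carnitine, and the replicate numbers 1 to 5 occur in both groups. Per the labels, the study held 60 mice, 30 per diet, in cages of 5 from the age of 3 weeks, and 10 mice per diet were killed at each of 9, 15 and 18 months. The labels do not say which of these ages the array mice had, so age may differ between the arrays and was not used here. The basal diet held less than 5 mg carnitine per kg, and the carnitine diet had 1000 mg L-carnitine per kg added. RNA came from 30 mg of frozen muscle, with a stated A260/A280 ratio of 1.87 ± 0.02 in each group, and the array samples were picked at random from each group.

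The deposited values are on the log2 scale with 2 decimals, 34390 probe sets on each array, and per the submitters' processing notes they were made with RMA in Affymetrix Expression Console, whose versions are not given in the sources used here. RMA subtracts background, brings the arrays to a shared intensity distribution and summarises the probes of a set, so a difference in total RNA per sample cannot be seen in these values, and dim probe sets are drawn towards a floor that shrinks their differences. The deposited arrays still differed in range, with an interquartile range from 2.20 to 2.59, so their distributions were not identical. No genome build is named, and no coordinates are given here. Probe sets were named from the platform's annotation table: 23521 have exactly 1 gene symbol, 1814 have several, and 9055 are not listed in the table and stay unnamed here. Only probe sets with 1 symbol entered the gene tests. Of the genes, 1082 had more than 1 such probe set, and the one with the highest mean over the 10 arrays was kept, which left 22180 genes. Cpt1b shares its probe set with other genes and is not reported.

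Carnitine was compared with control by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over all genes and a two-sided threshold of 0.05. No probe set was removed for a dim signal. A looser count took genes with an unadjusted p below 0.05 and at least a 1.5-fold difference. Before the data were examined, 43 lists of pathway genes and of markers of cell types were fixed, with 999 members in all. Of these members 891 were found, and 41 lists had at least 5 measured genes. The list of mitochondrially encoded transcripts and that of erythrocyte genes had too few and were not analysed here. Each list was tested with limma's camera at a preset correlation between genes of 0.01, which asks whether its genes rank differently from all other genes. The same lists were tested with camera and an estimated correlation, with fry, and by an exact two-sided permutation test of the list score, which is the mean log2 value over the list in each mouse. That test runs over all 252 assignments of 5 of 10 arrays and cannot give a p below 0.00794. After adjustment over 41 lists, 1 list alone at that p cannot pass 0.05, and several would have to reach it together. Member genes were also tested with p adjusted over the list alone.

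Apart from 6 genes named in the closing section after their values had been seen, the genes named in the text come from a rule fixed before the data were examined. It takes the 12 genes per direction with the largest change among those past the threshold, filled up to 12 with the smallest unadjusted p where fewer pass. It adds up to 4 members per list with the smallest unadjusted p and 23 genes of carnitine handling, muscle metabolism, atrophy and stress that are named whatever their result. Predicted genes, microRNAs, small nucleolar RNAs and olfactory or vomeronasal receptors were passed over in the first part and counted only. The rule takes 202 genes, and the text names 97 of them, chosen after their values had been seen.

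The fit was tested on simulated data with the same 22180 genes and 200 changed genes, in 20 simulations. It recovered 67.5% of genes changed 1.5-fold, 95.7% of those changed 2-fold and 99.2% of those changed 3-fold, and 4.35% of its calls were false. The simulated noise was independent between genes and alike on all arrays, unlike that of the real arrays, so these rates may not hold for the real data. In the real data the median standard error of a log2 difference was 0.110, and the median half-width of the 95% confidence interval was 0.236. The number of arrays limits this precision.

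The alternatives were a block for the replicate number, a filter on dim genes, other variance models, array weights, median centring and cyclic loess on top of the deposited values, all probe sets, the mean of a gene's probe sets, other thresholds, and the omission of each array in turn. Other splits of the 10 arrays were drawn 100 times, the real split included. Alternatives of the list score are given for 13 lists, a choice made after the values of all 41 had been seen. The spread between mice was compared through each gene's standard deviation within a group. No arrays held identical values, and each was counted as 1 mouse. The labels name separate RNA samples of mice, and which of them shared a cage is not stated.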

Results

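The study asked how lifelong L-carnitine feeding affects the skeletal muscle transcriptome of mice at advanced age. Gastrocnemius RNA from 5 mice on a low-carnitine basal diet (control) and 5 mice on the same diet with added L-carnitine (carnitine) was hybridised to 1 array each. L-carnitine carries long-chain fatty acids into mitochondria for oxidation. Expression values are RMA log2 values, and differences are given as carnitine minus control. Correlations between arrays, taken across genes, ran from 0.973 to 0.994. Control replicate 5 stood apart, with an interquartile range of 2.20 against 2.39 to 2.59 on the other 9 arrays and a mean of 6.76 over 73 small nucleolar RNA genes against 7.33 to 7.94.

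The largest differences among the named genes were in B4galnt2 (1.64) and, equal in size, the slow-fibre gene Myh7 described below (-1.64). B4galnt2 encodes the glycosyltransferase that makes a glycan of the neuromuscular junction. B4galnt2 averaged 5.78 ± 0.72 in control and 7.42 ± 0.40 in carnitine muscle (SD, n = 5 per group), a 3.11-fold higher level, and all 5 carnitine mice lay above every control. Its control mean lay at the median probe set level of 5.80, where the signal is weak, so the fold is uncertain. Ostn, which encodes the secreted muscle peptide osteocrin (musclin), averaged 9.11 ± 0.74 in control and 10.17 ± 0.26 in carnitine (difference 1.06, SE 0.27). Perp, a p53 target and desmosome component, averaged 6.87 ± 0.70 and 7.98 ± 0.40 (difference 1.11, SE 0.28). None of these passed limma's adjusted threshold: the adjusted p was 0.34 for B4galnt2 and 0.71 for both others. Without control replicate 2, whose B4galnt2 level of 6.97 lay above the 5.18 to 5.9 of the other controls, the difference in B4galnt2 was 1.94 with an adjusted p of 0.0040, and it was then the 1 gene past the threshold. The gap rule used below did not flag that mouse for B4galnt2. Its adjusted p in limma was 0.88 without control replicate 4, 0.52 without carnitine replicate 1 and 0.66 after median centring.

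Tppp3, a tubulin-binding protein, differed by 0.56 (SE 0.11), and Ahcy, the hydrolase that clears S-adenosylhomocysteine, by 0.45 (SE 0.11). Other genes with small p on the higher side were Pcdh7 (0.48), Gnai3 (0.47), Klk1 (0.46), Itfg1 (0.44), Cuta (0.37), the cyclin gene Ccnd1 (0.37) and Prl8a1 (0.34). On the lower side stood Slc22a13b (-0.54), Cyp4a31 (-0.51), Klk1b9 (-0.50), Reg2 (-0.48), Zfp353-ps (-0.47), Cabp7 (-0.46), Klk1b8 (-0.45), Skint4 (-0.43), Stfa2l1 (-0.43), Mycs (-0.40), Tspan10 (-0.39) and Pnliprp1 (-0.29). Cyp4a31 and the Klk1b genes have close paralogs whose transcripts the probes may share, so their values are uncertain. All 12 genes on the lower side, with Klk1 and Prl8a1, averaged at or below the median probe set level of 5.80, where the signal is weak.

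**Figure D1:**
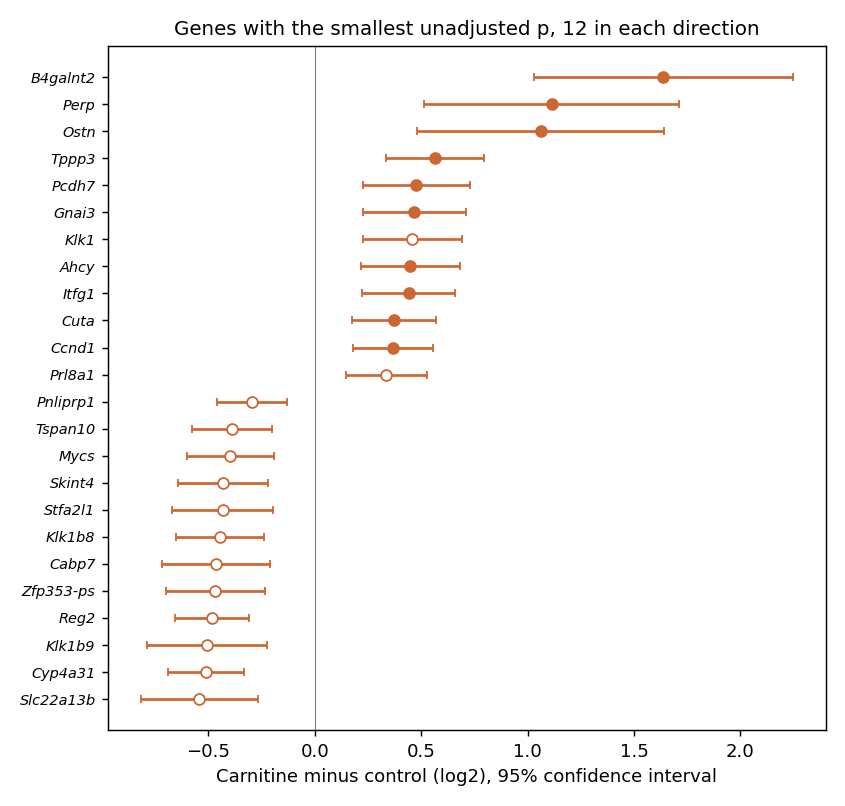
Difference between carnitine and control (x axis, log2) with its 95% confidence interval for the named genes with the smallest unadjusted p, 12 in each direction, from 5 mice per group; open circles mark genes whose mean lies below the median probe set level of 5.80. B4galnt2, Perp and Ostn lie between 1.06 and 1.64, and none of the genes passed the adjusted threshold.

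Of 22180 genes, 0 passed an adjusted p of 0.05 in limma, the smallest adjusted p was 0.34, and 1546 had an unadjusted p below 0.05 (696 higher, 850 lower) where 1109 would be expected by chance. A 1.5-fold difference with an unadjusted p below 0.05 was found in 28 genes, 14 higher and 14 lower, and 9 of the 14 lower genes are on the slow-fibre list. In 247 genes, or 1.11%, the groups did not overlap, against 0.794% by chance. The count of 28 was 69 without control replicate 2, 47 without carnitine replicate 4 and 18 without carnitine replicate 5, and after median centring 21 were higher and 10 lower.

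Slow-fibre genes were lower on average in carnitine muscle, with a wide spread between the mice. Myh7, the slow myosin heavy chain, averaged 10.68 ± 0.44 in control and 9.05 ± 1.93 in carnitine (SD, n = 5 per group), a difference of -1.64 (SE 0.67). Tnnc1, the slow troponin C, differed by -1.45 (SE 0.57), the stretch-responsive Ankrd2 by -1.33 (SE 0.43), the slow calcium pump gene Atp2a2 by -1.21 (SE 0.47) and the muscle LIM protein gene Csrp3 by -0.89 (SE 0.30). Of 15 measured slow-fibre genes, 13 had a negative difference, 10 of these with an unadjusted p below 0.05, and 0 passed adjusted over all genes or adjusted over the list alone (lowest p 0.054). Carnitine replicates 1, 2 and 5 had slow-fibre scores of 8.83, 8.30 and 7.75, under every control, while replicates 3 and 4, at 9.62 and 9.83, lay within the control range of 9.34 to 10.04. The score averaged 9.65 ± 0.35 in control and 8.86 ± 0.87 in carnitine (difference -0.79, exact permutation p = 0.119, adjusted 0.586). In camera at the preset correlation the list was lower with an adjusted p of 2.34e-06, but the adjusted p was 0.560 with an estimated correlation. Without carnitine replicate 5 the score difference was -0.51 (exact permutation p = 0.206) and without carnitine replicate 4 it was -1.03 (0.0397), the only omission of an array with a p below 0.05.

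**Figure D2:**
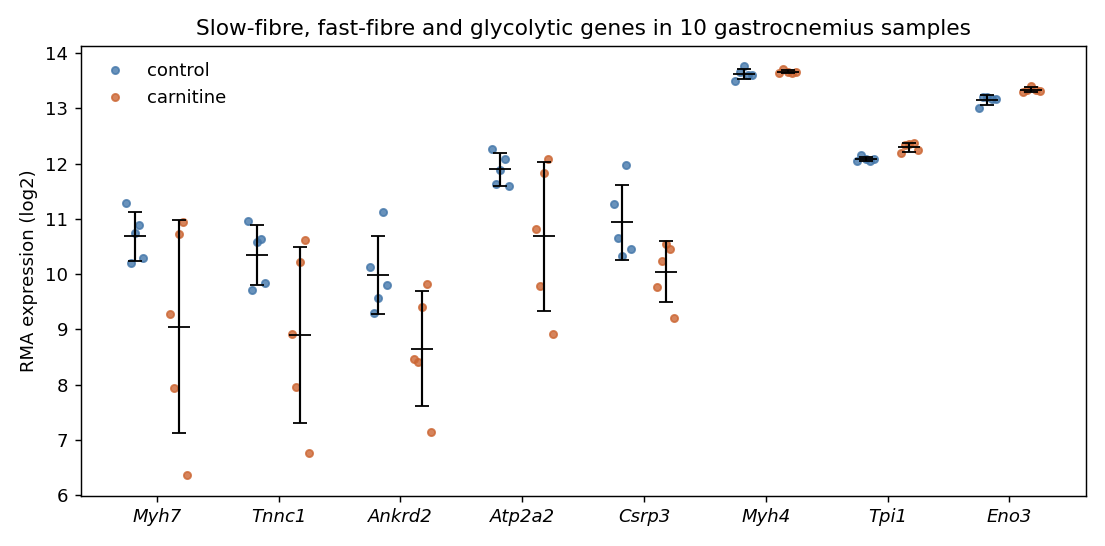
RMA log2 expression (y axis) of slow-fibre genes (Myh7, Tnnc1, Ankrd2, Atp2a2, Csrp3), the fast myosin gene Myh4 and the glycolytic genes Tpi1 and Eno3 in each mouse, with the mean and SD of the 5 mice per group as black bars. Myh7 averaged 10.68 in control and 9.05 in carnitine with SDs of 0.44 and 1.93, while Myh4 averaged 13.62 and 13.66.

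Of 21 measured genes of glycolysis and glycogen metabolism, 19 had a positive difference, among them triose phosphate isomerase Tpi1 (0.22, SE 0.068), the muscle enolase Eno3 (0.19, SE 0.066), Ugp2 of glycogen synthesis (0.24, SE 0.085) and the muscle phosphofructokinase Pfkm (0.18, SE 0.071). Tpi1, Eno3 and Ugp2 were higher in all 5 carnitine mice than in any control, and 0 of the 21 passed adjusted over all genes or adjusted over the list alone. The glycolysis score differed by 0.12 (exact permutation p = 0.0159, adjusted 0.217) and by 0.04 after cyclic loess. Camera called the list higher with an adjusted p of 2.34e-06, and the adjusted p was 0.502 with an estimated correlation. Of 18 fast-fibre genes, 15 had a positive difference, with Myoz3 at 0.25 (SE 0.089), Myoz1 at 0.22 (SE 0.080) and Ampd1 at 0.22 (SE 0.087), and 0 passed adjusted over the list alone. The fast myosin gene Myh4 differed by 0.04 (SE 0.066), a sign that turned after cyclic loess. The fast-fibre score differed by 0.09 (exact permutation p = 0.0317, adjusted 0.325) and by 0.01 after cyclic loess, where the median gene turned to -0.01, and camera gave an adjusted p of 0.000647, against an adjusted p of 0.560 with an estimated correlation.

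Slc22a5, the main plasma membrane carnitine transporter, averaged 6.42 ± 0.36 in control and 6.46 ± 0.10 in carnitine (SD, n = 5 per group). The differences were 0.03 in Cpt2 (SE 0.13), -0.02 in Crat (SE 0.091), 0.17 in the carnitine-acylcarnitine carrier Slc25a20 (SE 0.15), -0.05 in Bbox1 (SE 0.11) and 0.16 in Tmlhe (SE 0.13), the last 2 enzymes of carnitine synthesis, and the signs of Slc22a5, Cpt2, Crat and Bbox1 turned under at least 1 other scaling, array weighting or omission of an array. Of the 14 measured genes of the list, 7 had a positive and 7 a negative difference, and 0 passed adjusted over all genes. Adjusted over the list alone, 1 passed: Slc22a21, a carnitine transporter related to Slc22a5 with a weak signal (mean 5.71, below the median probe set level of 5.80), fell by 0.38 (SE 0.10, p adjusted over the list 0.039, 5 of 5 carnitine mice below every control, adjusted p = 0.71 over all genes). Other members were Cpt1c at -0.14 and Aldh9a1 at -0.24. The score of the list differed by -0.02 (exact permutation p = 0.722), a sign that turned after median centring, and camera gave an adjusted p of 0.587.

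Mitochondrial beta-oxidation genes averaged 9.45 ± 0.22 in control and 9.44 ± 0.20 in carnitine (list score, SD, n = 5 per group, exact permutation p = 0.944), with a difference of -0.01 that turned positive after median centring and was -0.09 after cyclic loess (camera adjusted p 0.106), with 11 positive and 12 negative of 23 members, Acad9 at 0.20 and Acot2 at -0.23. Of 17 PPAR targets, genes driven by the nuclear receptors that sense fatty acids, 15 had a negative difference, with Pdk4 at -0.36 (SE 0.29) and Fgf21 at -0.18 (SE 0.099), while Ucp3 differed by 0.004, which turned negative after cyclic loess. The PPAR score differed by -0.10 (exact permutation p = 0.317), the camera adjusted p was 0.103, and it became 0.0143 after cyclic loess, with a score difference of -0.15. In the deposited values the adjusted p was 0.691 with an estimated correlation. Among the lists that camera did not call, 4 had a median difference below the central 95% of random lists matched on mean signal: PPAR targets (-0.09, percentile 0), beta-oxidation (-0.01, percentile 0.04), immediate early genes (-0.03, percentile 0.28) and IGF1 and mTOR signalling (0.02, percentile 0.29). Random lists ignore the correlation between members, estimated at 0.16 for PPAR targets and 0.61 for beta-oxidation, so these percentiles may overstate how unusual the lists are. None of the members of these 4 lists passed adjusted over all genes or adjusted over the list alone.

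**Figure D3:**
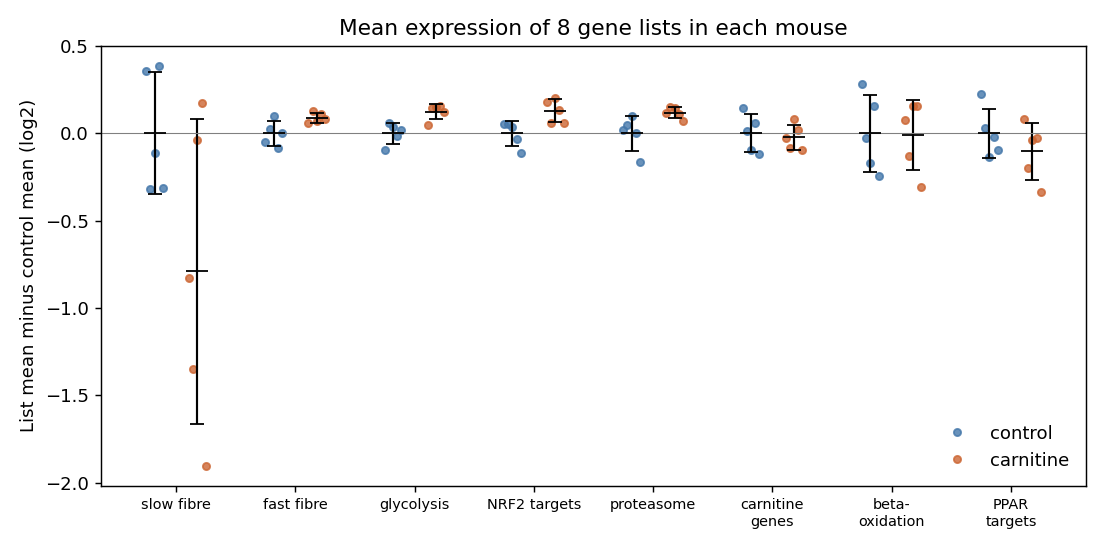
Mean log2 expression of 8 gene lists in each mouse minus the mean of the control mice (y axis), with the mean and SD of the 5 mice per group as black bars. The slow-fibre score differed by -0.79 with an SD of 0.87 among carnitine mice, and the carnitine gene score by -0.02.

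Of 73 oxidative phosphorylation genes, 65 had a positive difference, such as Cox7b at 0.30 (SE 0.15), while Sdha, a subunit of complex II and an enzyme of the tricarboxylic acid cycle, stood at -0.17 (SE 0.085). The score differed by 0.10 (exact permutation p = 0.460) and by 0.01 after cyclic loess. Camera called the list higher with an adjusted p of 2.33e-05, against an adjusted p of 0.754 with an estimated correlation and 0.173 without control replicate 5. Of 25 tricarboxylic acid cycle genes, 18 were positive (camera adjusted p = 0.0335, adjusted p = 0.754 with an estimated correlation), and this direction turned after cyclic loess. That call was lost without control replicate 3 (0.340) or 5 (0.203) and without carnitine replicate 3 (0.293) or 4 (0.178). Of 25 lipid synthesis genes, 20 were positive, with the desaturase genes Fads1 at 0.29 (SE 0.10) and Fads2 at 0.22 (SE 0.091), the cholesterol synthesis gene Cyp51 at 0.53 (SE 0.23) and malic enzyme Me1 at 0.39 (SE 0.17). The camera adjusted p of the list was 0.0137, against an adjusted p of 0.560 with an estimated correlation and 0.173 without control replicate 5. No member of these 3 lists passed adjusted over the list alone. Ppargc1a, the regulator of mitochondrial biogenesis, differed by 0.01 (SE 0.12), a sign that turned after cyclic loess, and its list of 20 genes was not called by camera (adjusted p 0.112).

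Of 34 proteasome subunit genes, 31 had a positive difference, with Psmd6 at 0.30 (SE 0.092) and Psmf1 at 0.30 (SE 0.11), and the score differed by 0.12 (exact permutation p = 0.0159, adjusted 0.217) and by 0.03 after cyclic loess. Camera gave an adjusted p of 2.34e-06, and the adjusted p was 0.560 with an estimated correlation. Of 27 autophagy genes, 25 were positive, with Gabarapl2 at 0.30 (SE 0.098). That score differed by 0.12 (exact permutation p = 0.0397, adjusted 0.325) and by 0.04 after cyclic loess, with a camera adjusted p of 2.37e-05 and an adjusted p of 0.560 with an estimated correlation. Of 31 NRF2 targets and antioxidant enzymes, 27 were positive, with the epoxide hydrolase Ephx1 at 0.45 (SE 0.13), Gstm2 at 0.33 (SE 0.12), Nfe2l2, which encodes NRF2 itself, at 0.25 (SE 0.10), Nqo1 at 0.26 (SE 0.14) and Hmox1 at 0.09 (SE 0.093). The NRF2 score was higher in all 5 carnitine mice than in any control, from 8.31 to 8.46 against 8.14 to 8.31, with an exact permutation p of 0.00794, the smallest the design allows, and 0.217 after adjustment over 41 lists, and the score difference went from 0.13 to 0.06 after cyclic loess. Camera gave 2.59e-05, and the adjusted p was 0.560 with an estimated correlation. In these 3 lists 0 members passed adjusted over all genes or adjusted over the list alone.

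None of the atrophy and stress genes named in advance passed adjusted over all genes. The muscle ubiquitin ligase genes Fbxo32 and Trim63 differed by -0.03 (SE 0.20) and 0.04 (SE 0.20), Mstn (myostatin) by 0.48 (SE 0.30), Igf1 by 0.08 (SE 0.17), the chaperone gene Hspa5 by -0.09 (SE 0.10), Ddit3 by 0.03 (SE 0.16), Atf4 by 0.02 (SE 0.079), Tnf by -0.07 (SE 0.11) and Il6 by -0.02 (SE 0.093). The signs of Fbxo32, Trim63, Igf1, Ddit3, Atf4, Tnf and Il6 turned under at least 1 other setting. Usp14 (0.31, SE 0.11) and Rheb (0.25, SE 0.088) had the smallest p in the atrophy and the IGF1 and mTOR lists. The camera adjusted p was 0.124 for 24 atrophy genes, 0.389 for 28 genes of IGF1 and mTOR signalling, 0.498 for 34 genes of the unfolded protein response, 0.443 for 31 NF-kB targets and 0.540 for 25 interferon response genes. Of 19 heat shock genes (camera adjusted p 0.0550), Hspe1 differed by 0.35 (SE 0.11) and Hspb8 by 0.27 (SE 0.087). In the cell cycle list of 27 genes, Ccnd1 rose by 0.37 adjusted over the list alone (p 0.0256, adjusted p = 0.71 over all genes), and Kif11 stood at -0.29 (SE 0.088).

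Of 35 extracellular matrix genes, 29 had a positive difference, with thrombospondin Thbs1 at 0.48 (SE 0.16) and periostin Postn at 0.40 (SE 0.18), and camera gave an adjusted p of 0.000153, against an adjusted p of 0.597 with an estimated correlation. The score of that list differed by 0.14 (exact permutation p = 0.175). Of 14 fibroblast markers, 13 were positive, with Dcn at 0.36 and Lum at 0.37 (score difference 0.17, camera adjusted p 0.00343, and adjusted p = 0.691 with an estimated correlation). Of 15 tendon and cartilage markers, 10 were positive, with Thbs4 at 0.44 (SE 0.18) and Chad at 0.48 (SE 0.20). Their score differed by 0.17 (exact permutation p = 0.135), with a camera adjusted p of 0.0230, an adjusted p of 0.560 with an estimated correlation 0.245 without carnitine replicate 3 and 0.0857 without control replicate 1, and the fibroblast call was lost without carnitine replicate 1 (0.0829) or control replicate 4 (0.0807). Of 14 pericyte and smooth muscle markers, 11 were positive (camera adjusted p 0.025, adjusted p = 0.560 with an estimated correlation), a call lost without control replicate 3 (0.135) or 5 (0.0631) or carnitine replicate 2 (0.0619). All 12 T cell markers were negative, with Cd2 at -0.28 (SE 0.14) and Cd8a at -0.24 (SE 0.14), and so were 11 of 12 neutrophil markers, with Elane at -0.25 (SE 0.094). Camera gave adjusted p values of 0.00590 and 0.0137 for these lists, and the adjusted p was 0.560 for each with an estimated correlation. In control the T cell markers averaged 5.50 ± 0.18 and the neutrophil markers 5.00 ± 0.15. Both lie below the median probe set level of 5.80, where the signal is weak. Control replicate 5 had the highest of the 10 T cell scores at 5.75. Without that array the camera adjusted p of the T cell list was 0.0563, and the neutrophil call was lost without control replicate 4 (0.0879) or carnitine replicate 3 (0.0505).

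Other cell type markers were not called. Among 13 adipocyte markers Retn differed by -0.38 (SE 0.15) and Adipoq by -0.33 (SE 0.16), with a camera adjusted p of 0.252 for the list, and among 20 macrophage markers (0.498) Cd163 differed by -0.24 and Cd68 by -0.17. Myf5, a gene of muscle stem cells, differed by 0.27 (SE 0.12), and Chrng, the fetal acetylcholine receptor subunit, by -0.42 (SE 0.17), in lists with adjusted p of 0.587 and 0.752. Igfbp7 of the senescence list differed by 0.22 (SE 0.084, list p 0.566). Perp rose by 1.11 adjusted over the epidermis list alone (p 0.0144, adjusted p = 0.71 over all genes), while Krt14 of the same list stood at 0.30 and camera gave 0.540. For the remaining lists, camera's adjusted p was 0.103 for clock genes, 0.155 for ribosomal proteins, 0.134 for B cells, 0.752 for mast cells, 0.566 for dendritic cells, 0.326 for endothelium, 0.832 for Schwann cells, 0.566 for brown adipocytes, 0.832 for immediate early genes and 0.566 for the cell cycle. In 7 lists, none of them called, the score, the median gene and camera did not share a sign, among them the carnitine, beta-oxidation and mast cell lists.

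Across the 41 lists, camera at the preset correlation called 15, of which 12 were higher and 3 lower. With an estimated correlation or by fry 0 were called. The exact permutation test after adjustment also called 0, which decides little, since 1 list alone cannot pass it (5 lists had an unadjusted exact p below 0.05). In 3 of the 41 lists a gene passed adjusted over the list alone (Slc22a21, Ccnd1 and Perp). That adjustment does not allow for the number of lists tried, so a few such genes can arise by chance. The differences also followed the expression level: the median difference was -0.07 in the dimmest 10% of genes and 0.09 in the brightest, and after cyclic loess, which removes such a trend, 1 of the 15 lists, that of slow-fibre genes, stayed called. The score differences of 13 of the other 14 lists shrank, that of the matrix list from 0.14 to 0.09, while that of the tendon list was 0.17 before and 0.18 after (camera adjusted p 0.0857).

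**Figure D4:**
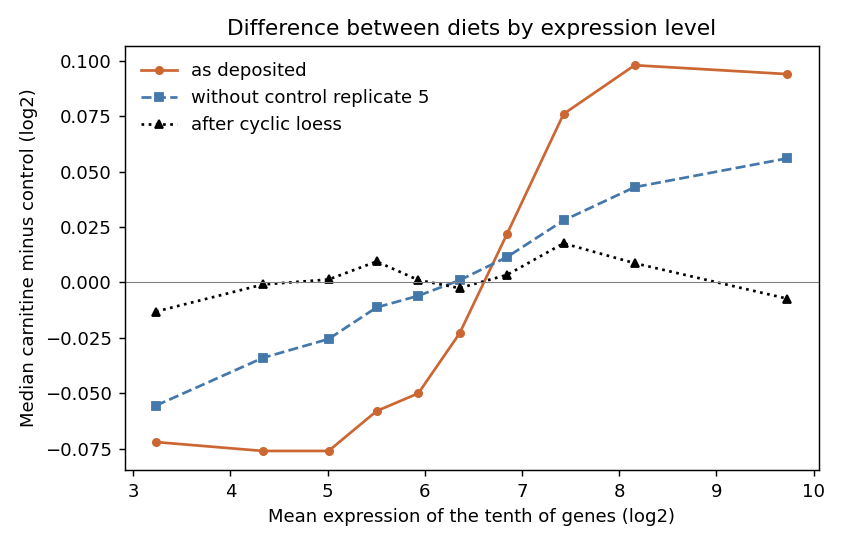
Median difference between carnitine and control (y axis, log2) in 10 equal groups of genes ordered by mean expression (x axis, log2), for the deposited values, without control replicate 5 and after cyclic loess. The median ran from -0.07 in the dimmest to 0.09 in the brightest group in the deposited values, and from -0.06 to 0.06 without control replicate 5.

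Expression varied less between carnitine mice than between control mice in most genes. The median standard deviation of a gene was 0.197 among controls and 0.133 among carnitine mice. The median log2 ratio of the standard deviations was -0.51 (permutation p = 0.0238). Without control replicate 5 the ratio was -0.23 (permutation p = 0.0397). Both permutations moved values from which each group's mean had been removed, so their p-values are approximate. The arrays also differed in signal range, and the spread was not compared after cyclic loess. Of the 15 slow-fibre genes, 10 had a larger standard deviation in carnitine, such as Myh7 (0.44 in control, 1.93 in carnitine) and Atp2a2 (0.29 and 1.35), while Csrp3 had 0.68 and 0.55.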

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

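The tests of a compressed signal range in control replicate 5 were chosen after its narrow range had been seen, and the test of immune cells before. Within each group of 5 mice, array measures, list scores and named genes were searched for a mouse far from the rest by the gap between it and its neighbour relative to the range (critical value 0.71). Of 288 groups examined, 12 had such a mouse, and chance gives about 1 in 20. The genes searched were shortened to those the text names after a first search had been seen. Over all 202 genes of the naming rule, all lists and all array measures, 38 of 508 groups had such a mouse.

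Control replicate 5 had a mean correlation of 0.978 with the other controls, whose values were 0.985 to 0.986, and the lowest levels in its group of the chaperonin gene Hspe1, 5.94 against 6.32 to 6.45, and of the myogenic factor Myf5, 5.84 against 6.25 to 6.40. As a technical explanation, its signal range was compressed: its gene values followed the mean of the other arrays with a slope of 0.910, below the 0.972 to 1.03 of the other 9 arrays. Removing this trend by cyclic loess left its mean correlation with all other arrays at 0.983 (0.978 before), still below the 0.988 to 0.991 of the others. This argues against a trend in scale as the whole cause. Loess cannot restore signal lost to noise in a compressed range, so compression in that sense is not excluded. Immune cells in the sample were tested as another source, and 0 of the 4 immune marker lists lay above random lists matched on mean signal, while endothelial markers and oxidative phosphorylation genes lay below them. Such random lists ignore the correlation between members, so endothelial and oxidative phosphorylation genes may stand out too easily. Whether anything else sets this array apart stays open, with lower RNA quality untested and no biological explanation other than immune cells tested.

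The interferon response score of control replicate 2 was 6.79, against 6.27 to 6.39 in the other controls. Carnitine replicate 5 had the highest circadian clock score of its group, 8.57 against 8.39 to 8.43, and a Schwann cell and nerve score of 6.69 against 6.14 to 6.27. Its Cuta level was 9.34, against 9.59 to 9.65 in the other carnitine mice. Carnitine replicate 2 had a Myh4 level of 13.71, against 13.64 to 13.66, and carnitine replicate 3 an Elane level of 5.65, against 5.88 to 5.96. Among controls, replicate 1 had an Eno3 level of 13 (others 13.17 to 13.21), replicate 3 a Ugp2 level of 11.28 (others 11.56 to 11.61) and replicate 2 a Rheb level of 10.09 (others 9.73 to 9.83).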

How the results depend on the processing

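The fit with the slow-fibre score as a covariate and the spread without control replicate 5 were chosen after seeing the data, and the other alternatives before. Under the alternatives that kept all arrays, 0 genes passed an adjusted p of 0.05 in limma, and 0 at 0.1. Omitting single arrays gave 0 to 1 gene, the 1 without control replicate 2. The 28 genes at 1.5-fold became 919 at 1.2-fold, 10 at 2-fold, 18 with a robust variance model, 94 over all probe sets, 54 with the slow-fibre score as a covariate, and 18 to 69 with 1 array omitted. The 15 lists called by camera became 9 above the median signal, 2 after cyclic loess, 0 with an estimated correlation, 0 with fry, and 11 to 19 with 1 array omitted. Above the median signal, lists left with fewer than 5 genes were not tested, so part of that drop may be lists not tested. The slow-fibre call was kept under the settings run except with an estimated correlation (adjusted p 0.560) and fry (0.592), which account for correlated members, and its score difference ran from -1.03 to -0.51 with 1 array omitted and was -1.33 as a median over the list. The exact test called 0 lists under each setting run, which decides little, since 1 list alone cannot pass its adjusted threshold. With the replicate number as a block, 0 genes passed, 35 reached 1.5-fold, camera called 16 lists, and the slow-fibre score difference stayed -0.79 (exact sign-flip p = 0.125). Same-numbered mice of the diets correlated from -0.13 to 0.24, over 0.1 in 3 of 5 pairs, and 2 of 5 controls correlated best with their own number, so the numbers were not taken to pair mice. Signal over background limits the dim genes on the lower side, and Klk1 and Prl8a1 on the higher side.

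Near-zero values turned sign, and the cause was not tested. Over all 202 genes of the naming rule 16 turned under scaling, array weights or omission of an array, 14 of them named in the text. Score signs turned in 22 of all 41 lists, but in 2 of the 13 lists whose values are given, a choice made after all had been seen. After cyclic loess the tricarboxylic acid cycle list pointed down (adjusted p 0.461), and the differences were -0.077 for Cpt2, 0.018 for Bbox1, -0.10 for Ucp3, -0.094 for Ppargc1a, -0.024 for Myh4, -0.066 for Trim63, -0.024 for Ddit3, -0.078 for Atf4 and 0.047 for Il6. Array weights gave -0.048 for Slc22a5, -0.0049 for Cpt2, -0.047 for Ucp3, -0.040 for Ppargc1a, -0.065 for Trim63 and -0.097 for Ddit3. Median centring gave 0.034 for Crat, 0.018 for Fbxo32 and 0.032 for Il6, 0.027 for the carnitine list score and 0.041 for the beta-oxidation score. The carnitine score was 0.034 above the median signal, and the beta-oxidation score 0.035 as a mean of z-scores. With 1 array omitted, the ranges were -0.062 to 0.16 for Slc22a5, -0.044 to 0.11 for Cpt2, -0.088 to 0.03 for Crat, -0.093 to 0.032 for Bbox1, -0.17 to 0.11 for Ucp3, -0.046 to 0.097 for Ppargc1a, -0.20 to 0.11 for Fbxo32, -0.11 to 0.16 for Trim63, -0.048 to 0.18 for Igf1, -0.12 to 0.11 for Ddit3, -0.0035 to 0.054 for Atf4, -0.15 to 0.003 for Tnf, -0.070 to 0.017 for Il6, -0.052 to 0.013 for the carnitine score and -0.070 to 0.065 for the beta-oxidation score.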

Other observations

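Tests chosen after the result was seen are those of the count of 0 genes, of the lists against a signal-dependent difference and without control replicate 5, of the slow-fibre genes against chance and against a signal-dependent difference, and the fit with the slow-fibre score. Gamt, the enzyme that makes creatine from guanidinoacetate with S-adenosylmethionine, was singled out after its values were seen: it averaged 7.51 ± 0.48 in control and 8.13 ± 0.06 in carnitine (SD, n = 5 per group, adjusted p = 0.71 in limma), with all 5 carnitine mice above every control. Ahcy, which clears the by-product of such methyl transfers, averaged 7.30 ± 0.23 and 7.75 ± 0.09 (adjusted p = 0.71), again with 5 of 5 carnitine mice above every control.

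With diet and score in 1 limma fit over the 10 mice, 28 genes passed an adjusted p of 0.05 for the score, and 19 of these lie outside the slow-fibre list, so they were not part of the score. They include Ldhb, the lactate dehydrogenase subunit of oxidative tissue (slope 0.80 log2 per unit of score, adjusted p = 0.00028), the mitochondrial isocitrate dehydrogenase Idh2 (0.79, adjusted p = 0.00996), the transhydrogenase Nnt (0.62), the ketone body enzyme Bdh1 (0.60) and Fndc5 (0.50). These 5 were chosen after their values were seen. Without carnitine replicates 2 and 5, whose scores lay farthest from the median, 0 of the 19 passed the adjusted threshold (19 had an unadjusted limma p below 0.05, on mice from which they had been chosen), and the 5 genes that passed are all on the slow-fibre list. All 19 kept the sign of their slope without those mice. Fewer mice and a narrower range of scores also weaken the test, so whether the relation of the 19 genes to the score rests on those mice stays open. With the score in the fit, the difference between diets in B4galnt2 was 1.71, in Ostn 0.95 and in Perp 0.76, and 0 genes passed an adjusted p of 0.05 for diet.

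Splits of the 10 arrays that ignore diet do not let chance be excluded for the counts above 0. For the 0 genes past the adjusted threshold they decide nothing, since all 100 splits reach 0 by construction, with 2 as the highest of the others. The 1546 genes at an unadjusted p below 0.05 were reached by 17 splits, with 3610 as the highest other, the 28 genes at 1.5-fold by 32, with 123 as the highest other, and the 15 lists of camera by 28, with 23 as the highest other. The 123 genes of the highest other split are several times the real 28 (median of the others 20), which may reflect a structure among the mice apart from diet, and this was not tested further.

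The 15 lists that camera called were mostly bright lists pointing up and dim lists pointing down. A candidate explanation is a signal-dependent difference between the arrays, such as a wider signal range in the carnitine group. Against 10000 random lists matched on mean signal, 7 of the 15 lay outside the central 95% (oxidative phosphorylation, glycolysis, slow-fibre, matrix, T cell, fibroblast and tendon lists). That is the most allowed for this explanation by a limit written after the calls had been seen. With signal alone at work and independent members, far fewer would lie outside, so the count does not speak for signal as the whole cause. Random lists ignore the correlation between members, so this count may be too high, and the test does not decide. After cyclic loess 1 stayed called, the score difference going from 0.12 (SE 0.033) to 0.04 (SE 0.043) for glycolysis and from 0.12 (SE 0.047) to 0.03 (SE 0.020) for the proteasome; differences shrank in 13 of the 14 lists that lost the call, but for the tendon list it was 0.17 (SE 0.11) before and 0.18 (SE 0.11) after, so its lost call does not speak for this explanation. Control replicate 5 alone does not settle it, since 10 of the 15 stayed called without it, and a true rise of many abundant muscle transcripts stays open as the biological alternative for lists other than the slow-fibre one.

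The lower slow-fibre genes in 3 of 5 carnitine mice were weighed against chance, signal and tissue sampling. Of the 252 assignments of the mice, 30 gave a score difference as large, so chance is not excluded. A signal-dependent difference between arrays as the whole cause is argued against, since the score difference was -0.87 after cyclic loess (-1.12 to -0.60 with 1 array omitted) and -0.79 before. If the difference reflected the fibre mix that also varies among mice of one diet, for example through which part of the gastrocnemius the 30 mg came from, the 200 genes outside the list that follow the score most closely within a diet should differ between diets in proportion. Of these 200, 107 moved in the predicted direction, little more than an even split. All 200 lay above the median signal, and the test used the deposited values, before cyclic loess. In those values the median difference was 0.094 in the brightest 10% of genes. Such a rise works against the fall predicted for the 131 genes with a positive slope. It works with the rise predicted for the 69 with a negative slope, so the split is hard to read. The 200 genes were picked by their correlation with the score in these same mice. Their slopes may therefore be too steep, which draws the coefficient towards no shift. Without such a bias a shift in full proportion would give a coefficient of -0.79, and that of the 200 genes was -0.23 (-0.40 to -0.097 with 1 array omitted). That lies above the -0.4 set in advance as fitting, but not close enough to no shift to count against a fibre mix, so the test does not decide. An effect of diet on fibre type predicts the same shift, so sampling and diet cannot be told apart here either.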
